A study of chicken gut metagenome with 12 samples.

How the data were processed

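The samples were ileal contents of 12 male AA broilers, a fast-growing meat chicken, 3 from each of 4 groups (control and feed labelled with 0.5%, 1.0% or 2% green tea). Per the labels' protocols, 100 birds were placed in each of 4 rooms on wood shavings, and on day 42, after a 12-h fast, 3 birds per group were taken at random. Contents were scraped from the thawed ileum, DNA was extracted with a bacterial genomic kit, and the V3-V4 region of the 16S rRNA gene was amplified with primers 343F and 798R, barcoded at the forward primer, and sequenced together on a 454 FLX+ instrument. The replicates are therefore separate birds, but birds of a room share air, litter and droppings, and which room held which group is not stated.

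The authors deposited a table of OTU counts, whole numbers of reads per OTU and sample that had not been rarefied or scaled, with a taxonomic name from domain to genus for 1177 of the 3098 OTUs. How reads were filtered, how chimeras were removed, how OTUs were clustered and which classifier named them is not given in the sources used here. Names carry a percentage that reads as a bootstrap value, at 100 for 683 of the 730 OTUs with a named genus and at least 55 in all of them. The 1921 OTUs without taxonomy held 13.1% of counts, between 8.41% and 23.0% per bird, and the deposited column of OTU totals, a value of another kind, lists 0 for them. OTUs with a single count in the whole table numbered 1857, or 59.9%, which affects richness estimates. No OTU was named as chloroplast or mitochondrion. PCR reads are not independent molecules, primers amplify taxa unequally and genomes differ in 16S copies, so shares describe reads and not cells, and a rise in the share of a genus lowers that of the others.

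From these counts OTUs were summed by genus, giving 202 named genera. Genera with a total of at least 10 counts and a count in at least 3 samples were tested, 79 in all, which held 79.6% of counts. The main test was edgeR's robust quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) in a single fit of all 4 groups, with the total count of the sample as library size, so that counts without a genus stayed in the total, and with Benjamini-Hochberg adjustment at 0.05 within each contrast. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Contrasts were each tea group against control, the mean of the tea groups against control, 2% against 0.5% tea and a linear trend with tea percent. A fold against a group at 0 was computed from pooled counts against 3 counts over that group. It is a lower bound for counting error alone and does not cover the spread between birds. The fitted value depends on the prior count of 0.125 and is not a bound. Shares of phyla (mean share of at least 0.5%), of lists and diversity measures were tested by exact two-sided permutation of all assignments of birds to groups, with Benjamini-Hochberg adjustment over the phyla, lists or diversity measures. Composition was tested by an exact permutational analysis of variance. Permutation tests and summaries used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

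Both procedures were tested on simulated data. Counts for the 79 genera were drawn from the real means and library sizes in 30 simulations. Recovery was counted only among simulated genera that passed the count filter, so the share of all changes put in is lower. For the mean of the tea groups against control, 33 of 154 tested 4-fold changes (21.4%) were recovered. The same held for 118 of 150 tested 16-fold (78.7%) and 141 of 142 tested 64-fold changes (99.3%), with 0.453% of unchanged genera called. For 2% tea against control the shares of tested changes were 6.49%, 56.7% and 93.0%, with 0.509% of unchanged genera called. In these simulations each genus was drawn independently with the fitted dispersion, and a changed genus had the same fold in every tea group. Genera that vary together between birds, and rooms, were left out, so false calls may be more frequent in the real data. The permutation test called 5% of 200 unchanged measures and 88% of 50 measures shifted by 3 SD.

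The groups, tests, alternatives and lists of genera were set before the data were examined, as was the rule for the taxa named in the text. That rule took the phyla with a mean share of at least 0.5%, the 10 commonest genera, all genera passing a contrast if 20 or fewer and otherwise the 10 largest in each direction, the 5 genera with the smallest p where none passed, the 4 commonest tested members of each list, the 5 commonest OTUs and, among OTUs that passed, the 5 with the smallest adjusted p per contrast. The 7 lists with members in the table were lactic acid bacteria (9 genera, 8 seen, 7 tested), short-chain fatty acid producing Clostridia (14, 12, 8), genera holding enteric pathogens (13, 2, 1), segmented filamentous bacteria and related (7, 2, 2), hindgut Bacteroidetes (7, 3, 1), litter, skin and dust bacteria (13, 10, 8) and common reagent and water bacteria (18, 12, 5). Alternatives were TMM and TMMwsp factors, DESeq2 1.42.0 with poscounts size factors, a centred log-ratio of counts plus 0.5 with limma 3.58.1, no filter and a stricter filter (a total of at least 50 counts and a count in at least 6 samples), OTUs in place of genera, rarefied counts, a replicate block, fits of the 2 groups alone, a rank scale of dose, other distances and scales, and leaving out each bird. Fits with a library size from named genera, without the litter genera, with families in place of genera, and without OTUs lacking taxonomy were added after seeing the data.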

Results

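The bacterial community of the ileum, the last part of the small intestine, was profiled in 12 male broiler chickens from a trial of green tea powder in the feed. The birds formed 4 groups of 3, a control group without tea and groups labelled with 0.5%, 1.0% and 2% tea, and were sampled on day 42 after a 12-h fast. Sequences of the 16S rRNA gene, the bacterial marker gene used to name taxa, had been grouped by the authors into 3098 operational taxonomic units (OTUs, clusters of similar sequences). The 12 samples held 179927 counts, between 10631 and 17458 per bird, so that 3 counts, taken here as the smallest detectable share, corresponded to 0.0172% to 0.0282% of a sample. OTUs with a named genus held 79.9% of all counts, OTUs with an unclassified genus 6.97% and OTUs without any taxonomy 13.1%. Values are shares of all counts of a sample, given as mean ± SD over the birds of a group (n = 3), and the floors and the Wilson 95% intervals of single birds cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The labels say that the birds were reared in 4 rooms and do not say which group was kept in which room, so a difference between diets cannot be separated here from a difference between rooms.

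The ileal community was dominated in every group by genera that are common in poultry litter, on skin and in barn dust. Brevibacterium took 14.4% ± 7.18 of counts over the 12 birds, Brachybacterium 14.3% ± 6.43, Corynebacterium 12.2% ± 5.46, Jeotgalicoccus 10.5% ± 4.44 and Staphylococcus 5.98% ± 2.17 (SD, n = 12). Lactobacillus, a usual main genus of the chicken ileum, held 9.93% ± 12.0, followed by Clostridium_XI at 1.90% ± 1.82, Trichococcus at 1.12% ± 0.663, Facklamia at 1.08% ± 0.645 and Enterococcus at 0.814% ± 0.343. These 10 genera together held 72.2% of all counts. Among phyla, Actinobacteria held 36.7% ± 17.0 in control and 49.1% ± 3.07, 49.2% ± 24.6 and 38.5% ± 2.34 at 0.5%, 1.0% and 2% tea, while Firmicutes held 46.3% ± 12.1, 39.9% ± 3.18, 37.5% ± 22.2 and 45.3% ± 4.61 (SD, n = 3). Proteobacteria held 0.230% ± 0.174, 0.117% ± 0.0879, 2.62% ± 3.62 and 0.655% ± 0.337. The mean at 1.0% tea came mostly from tea 1.0% replicate 1, at 6.79% against 0.323% and 0.747% in replicates 2 and 3. None of the 3 phyla differed over the 4 groups in a two-sided exact permutation test of the F statistic, with p = 0.626 for Actinobacteria, 0.819 for Firmicutes and 0.152 for Proteobacteria and adjusted values of 0.819, 0.819 and 0.456. A centred log-ratio scale gave 1 phylum past the threshold.

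Whether tea at any dose changed the genera was asked by setting the mean of the 3 tea groups against control. Of the genera that passed, 17 were lower in the tea birds and 2 were higher. This contrast averages the fitted log values of the 3 tea groups, so a genus at 0 in a whole tea group can hardly pass as higher. In the family fit, Jonesiaceae had a log2 fold change of 6.07 at 2% tea. In this contrast it had 3.47 with a standard error of 8307. The excess of lower over higher calls may therefore be set in part by the test. Clostridium_XVIII fell from 1.95% ± 1.501 (SD, n = 3) in control to 0.0922% ± 0.148 in the 9 tea birds, 21.1-fold, and Erysipelotrichaceae_incertae_sedis from 0.784% ± 0.760 to 0.0495% ± 0.0785, 15.8-fold. Blautia, an acetate-forming member of the Lachnospiraceae, fell from 1.91% ± 1.41 to 0.219% ± 0.259 and Lachnospiracea_incertae_sedis from 1.07% ± 0.874 to 0.0839% ± 0.0747. Faecalibacterium, a butyrate producer of the caecum, fell from 0.275% ± 0.240 to 0.0174% ± 0.0293, Flavonifractor from 0.434% ± 0.620 to 0.00855% ± 0.0118, and Clostridium_IV from 0.261% ± 0.180 to 0.00546% ± 0.0113. Clostridium_XI, which the table places in the Peptostreptococcaceae, rose from 0.394% ± 0.107 to 2.40% ± 1.86 and lay above every control in 9 of 9 tea birds. Aerococcus, a facultative lactic acid bacterium, rose from 0.0762% ± 0.0316 to 0.607% ± 0.570 and lay above every control in 8 of 9 tea birds. Single birds moved some of these values. Flavonifractor took 1.15% (Wilson interval 0.992% to 1.33%) of counts in control replicate 1, and without that bird control held 0.0781%, 9.13-fold above tea. Without control replicate 2 the fold was 5.60 for Blautia, 7.95 for Erysipelotrichaceae_incertae_sedis and 9.06 for Faecalibacterium. Without tea 0.5% replicate 1 it was 44.4 for Clostridium_XVIII, 25.1 for Erysipelotrichaceae_incertae_sedis and 31.1 for Faecalibacterium.

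In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 19 of the 79 tested genera passed 0.05 in that contrast, 2 higher and 17 lower in tea. The fitted log2 fold change of Clostridium_XVIII was -4.83 with a standard error of 0.78 (adjusted p = 6.12e-05), of Blautia -3.41 with 0.72 (adjusted p = 0.000782) and of Clostridium_XI 2.32 with 0.63 (adjusted p = 0.00638). The other lower genera were Anaerofilum, Anaerofustis, Anaerostipes, Bacteroides, Bilophila, Butyricicoccus, Dorea, Peptococcus, Pseudoflavonifractor and Sharpea, each at 0.257% or less of control counts. Sharpea was at 0 counts in all 9 tea birds against 18 counts in control, at least 18.7-fold lower when 3 counts are allowed over the tea birds (at least 9.45-fold without control replicate 2). Clostridium_IV, Dorea, Anaerostipes and Sharpea were below every control bird in 9 of 9 tea birds. Of the 8 tested genera of short-chain fatty acid producing Clostridia, 7 fell and 1, Eubacterium, did not pass; adjusted over the list alone, 8 fell. Among the 7 tested lactic acid bacteria 1 rose, Aerococcus, and the single tested hindgut Bacteroidetes genus, Bacteroides, fell from 0.0622% ± 0.0784 to 0.00545% ± 0.00925. Control held 0.0173% Bacteroides without control replicate 1, and the tea birds 0.00307% without tea 0.5% replicate 1. Clostridium_XI rose among the 2 tested segmented filamentous bacteria and related genera. Adjusted over the list alone, each of these 3 lists gave the same count, and 0 members of the litter list passed, nor did a member of the pathogen and reagent lists in this or any other contrast. DESeq2 called 6 higher and 13 lower genera, and a centred log-ratio with limma 6 higher and 12 lower. A stricter filter on rare genera gave 10 calls among fewer tested genera, and 11 of the 19 calls held without any of the 12 birds in turn.

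**Figure D1:**
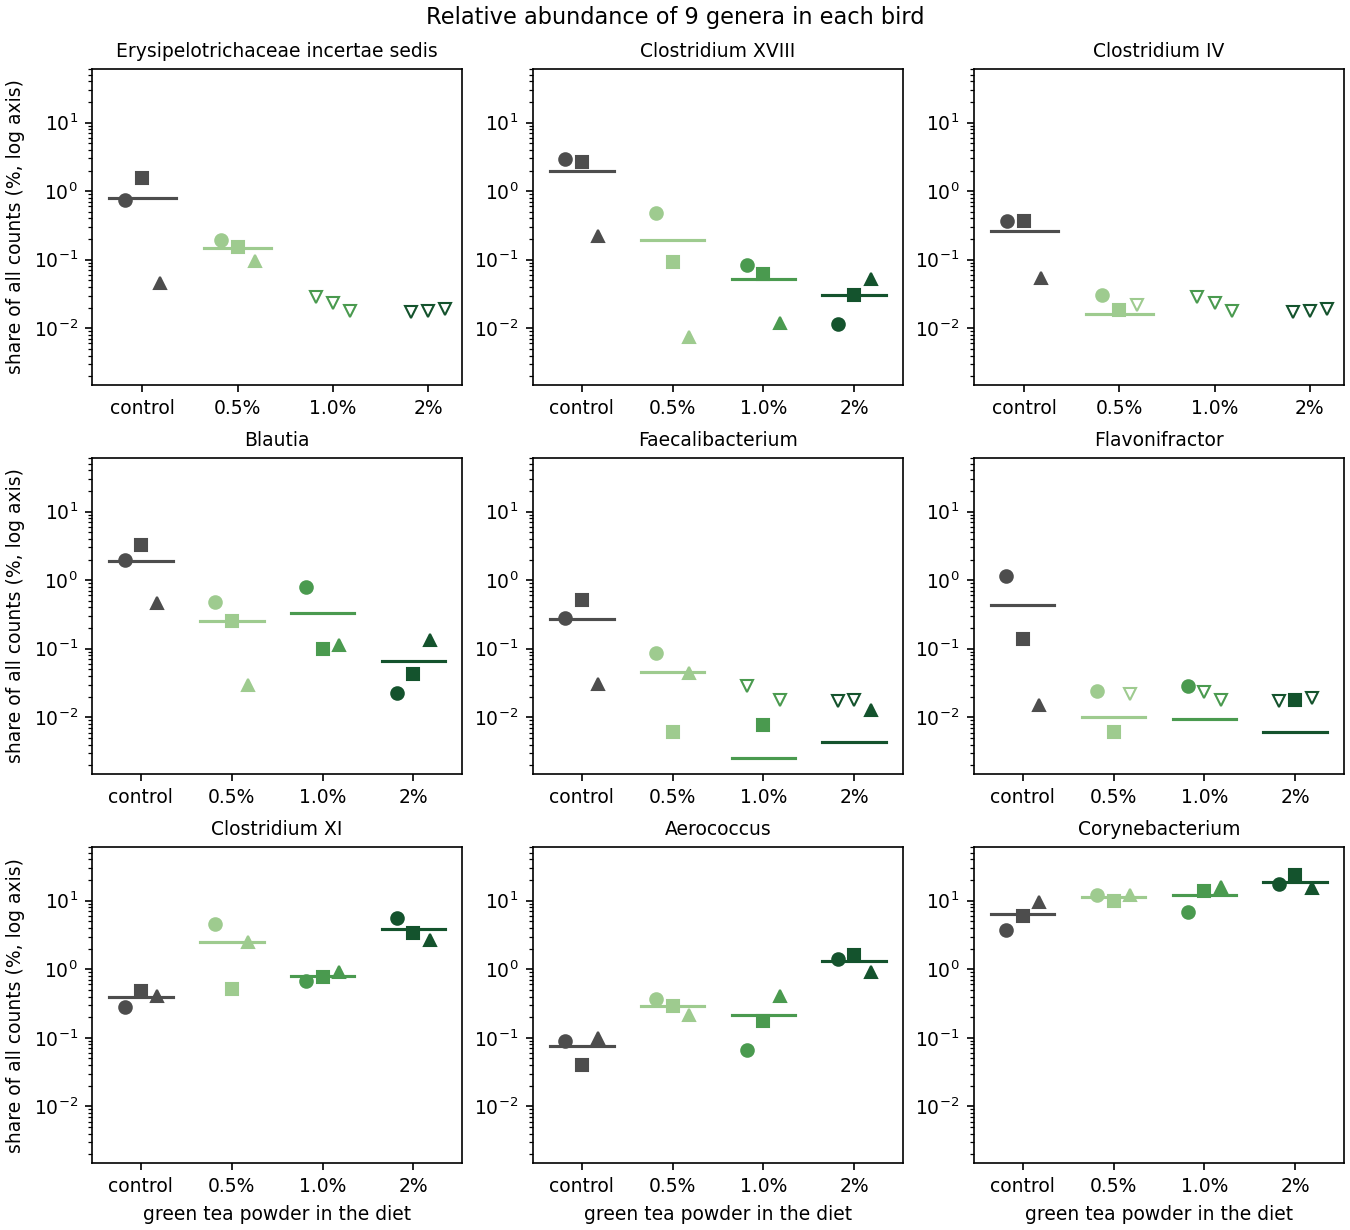
Share of all counts (%, log axis) of 9 genera in each of 12 birds by tea content of the diet; circles, squares and triangles are replicates 1, 2 and 3, horizontal lines are group means, and open downward triangles are birds at 0 counts drawn at the share of 3 counts. Erysipelotrichaceae_incertae_sedis was at 0 in all 6 birds given 1.0% or 2% tea, and Clostridium_XI lay above every control in 9 of 9 tea birds.

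The control birds were far apart in the lower genera. The 17 lower genera together held 10.1% of counts (interval 9.60% to 10.5%) in control replicate 1 and 11.9% (11.4% to 12.5%) in control replicate 2, but 1.01% (0.854% to 1.20%) in control replicate 3. The 9 tea birds ranged from 0.103% (0.0652% to 0.163%) to 1.55% (1.37% to 1.75%). Control replicate 3 lay at or below the highest tea bird in 13 of the 17 genera and above the mean of the tea birds in 10. Without control replicate 1 or control replicate 2, 15 genera passed in either case, of which 15 and 13 were among the 19, and without control replicate 3 there were 23. The calls of Aerococcus and Pseudoflavonifractor were lost without either of control replicates 1 and 2, those of Bacteroides and Flavonifractor without control replicate 1, those of Bilophila, Butyricicoccus, Dorea and Peptococcus without control replicate 2, and that of Pseudoflavonifractor also without tea 2% replicate 2. Without control replicate 2 Dorea was 4.90-fold, Butyricicoccus 3.601-fold and Peptococcus 1.58-fold lower in tea. Pseudoflavonifractor was 2.11-fold lower without control replicate 1 and 17.3-fold lower without tea 1.0% replicate 1. Across other settings the call of Bilophila held in 4 of 9, that of Pseudoflavonifractor in 5 of 10 and those of Anaerofustis and Bacteroides in 7 of 9. Anaerofilum and Sharpea were lost under DESeq2 alone and Peptococcus under a centred log-ratio alone.

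At 2% tea, the highest content, 7 genera were higher and 10 lower than in control. Clostridium_XI rose from 0.394% ± 0.107 to 3.89% ± 1.55 (SD, n = 3), 9.86-fold, Aerococcus from 0.0762% ± 0.0316 to 1.31% ± 0.370, 17.2-fold, and Weissella, a lactic acid bacterium, from 0.0331% ± 0.0234 to 0.496% ± 0.503, 15.0-fold. Weissella took 1.08% (interval 0.926% to 1.25%) in tea 2% replicate 3, without which the group held 0.206%, 6.21-fold above control, and did not pass (edgeR adjusted p = 0.120). Corynebacterium, the commonest genus to change, rose from 6.42% ± 2.95 to 18.6% ± 4.20, 2.90-fold. The scarce genera at 0 counts in control that also rose were Jonesia with 27 counts (at least 7.94-fold higher), Caryophanon with 22 (at least 6.47-fold) and Paracoccus with 21 (at least 6.18-fold), each against 3 counts over the control group. These 3 calls depended on the setting and on single birds. That of Jonesia held in 8 of 10 other settings and in 6 of the 12 runs without 1 bird, that of Caryophanon in 3 of 10 and 5 of 12, and that of Paracoccus in 6 of 11 and 6 of 12. Erysipelotrichaceae_incertae_sedis was at 0 counts, at least 135-fold lower than control, and Clostridium_IV likewise, at least 45.0-fold lower. Such bounds rest on pooled counts and do not cover the spread between birds. Erysipelotrichaceae_incertae_sedis had 117, 233 and 6 counts in control replicates 1, 2 and 3. Clostridium_XVIII fell to 0.0311% ± 0.0201, 62.8-fold, and Blautia to 0.0668% ± 0.0601, 28.6-fold. Faecalibacterium fell to 0.00430% ± 0.00744, Flavonifractor to 0.00603% ± 0.0104, Lachnospiracea_incertae_sedis to 0.0973% ± 0.128 and Yaniella, an actinobacterium of litter, from 0.0815% ± 0.0493 to 0.00607% ± 0.000361. The means of Faecalibacterium, Flavonifractor and Yaniella lay below the share of 3 counts in these birds, 0.0172% to 0.0193%. At such counts the small SD of Yaniella says little about the spread between birds. Pseudoflavonifractor and Anaerostipes were at 0, at least 14.0-fold and 9.07-fold lower. Among the lower genera, the call of Pseudoflavonifractor held in 8 of 11 other settings and in 7 of the 12 runs without 1 bird, that of Anaerostipes in 6 of 10 and 7 of 12, and that of Lachnospiracea_incertae_sedis in 8 of 11 and 8 of 12. The calls of Faecalibacterium, Flavonifractor and Weissella held in each of 11 other settings and in 10, 9 and 10 of the 12 runs. Without control replicate 2 the fold of Blautia was 18.3 and the bound of Erysipelotrichaceae_incertae_sedis 70.5, and without control replicate 1 the bound of Pseudoflavonifractor was 5.32. Without tea 2% replicate 3 the fold was 58.7 for Blautia and 45.5 for Lachnospiracea_incertae_sedis and the bound of Caryophanon 3.85. The bound of Caryophanon was 9.73 without tea 2% replicate 2 and that of Paracoccus 9.53 without tea 2% replicate 1.

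In this contrast 17 of 79 genera passed, 7 higher and 10 lower (edgeR, Benjamini-Hochberg), with log2 fold changes of 3.30 for Clostridium_XI (standard error 0.72, adjusted p = 0.00260), 4.09 for Aerococcus (0.91, adjusted p = 0.00260), 1.54 for Corynebacterium (0.49, adjusted p = 0.0336), -5.94 for Clostridium_XVIII (1.28, adjusted p = 0.00260) and -4.83 for Blautia (1.14, adjusted p = 0.00353). Of the 8 short-chain fatty acid producing Clostridia 5 fell and 3 did not pass, and 7 fell when adjusted over the list alone. Of the 7 lactic acid bacteria 2 rose, and of the 2 segmented filamentous bacteria and related genera Clostridium_XI rose. Of the 8 litter, skin and dust genera Corynebacterium rose, Yaniella fell and 6 did not pass. These 3 lists gave the same counts adjusted over the list alone. Corynebacterium lost its call without control replicate 1, control replicate 2 or any of the 3 birds at 2% tea, and under TMMwsp scaling, a centred log-ratio with limma and no filter on rare genera. The call of Yaniella held in 6 of 10 other settings and in 3 of the 12 runs without 1 bird. Lactobacillus was at 12.3% ± 5.53 against 4.56% ± 1.52 in control and did not pass (log2 fold change 1.44, standard error 0.67, adjusted p = 0.0976). TMMwsp scaling gave 6 higher and 18 lower genera. The count was 7 without control replicate 1, 11 without control replicate 2 and 26 without control replicate 3, 27 without tea 1.0% replicate 1, and 8, 9 and 8 without tea 2% replicates 1, 2 and 3. The calls of Clostridium_XI, Aerococcus, Blautia, Clostridium_IV, Clostridium_XVIII and Erysipelotrichaceae_incertae_sedis held in each of the 12.

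At 1.0% tea, 8 of the 9 genera that passed were lower. Erysipelotrichaceae_incertae_sedis was at 0 counts in the 3 birds, at least 109.9-fold lower than control, Clostridium_IV at 0, at least 36.7-fold lower, Anaerofilum at 0, at least 15.4-fold lower, and Anaerofustis at 0, at least 13.9-fold lower. The calls of Anaerofilum and Anaerofustis each held in 6 of 10 other settings and in 6 of the 12 runs without 1 bird. Clostridium_XVIII fell to 0.0527% ± 0.0372 (SD, n = 3), 37.0-fold, and Lachnospiracea_incertae_sedis to 0.0543% ± 0.0164, 19.7-fold. Faecalibacterium fell to 0.00256% ± 0.00444, a single count, and Flavonifractor to 0.00941% ± 0.0163, 3 counts. The call of Lachnospiracea_incertae_sedis held in 8 of 11 other settings and in 9 of the 12 runs, and that of Flavonifractor in 8 of 11 and 8 of 12. Paracoccus, at 0 in control, rose to 28 counts, at least 10.1-fold higher, a call that held in 9 of 11 other settings and in 6 of the 12 runs without 1 bird. Its bound was 6.34 without tea 1.0% replicate 1, and that of Erysipelotrichaceae_incertae_sedis 57.6 without control replicate 2. The test gave 9 of 79 genera, 1 higher and 8 lower (edgeR, Benjamini-Hochberg), with log2 fold changes of -5.21 for Clostridium_XVIII (standard error 1.24, adjusted p = 0.00742) and -4.29 for Lachnospiracea_incertae_sedis (1.20, adjusted p = 0.0228). Of the 8 short-chain fatty acid producing Clostridia 2 fell and 6 did not pass. Adjusted over the list alone, 7 fell and 1 of the 7 lactic acid bacteria, Lactobacillus, rose. Bacteroides also fell on that basis, but it was the only tested genus of its list, so its p was in effect not adjusted. Lactobacillus took 45.5% of counts (interval 44.5% to 46.4%) in tea 1.0% replicate 1 and 3.83% (3.51% to 4.18%) and 5.39% (5.06% to 5.74%) in the other birds of the group. TMM scaling left 2 genera and DESeq2 gave 4 higher and 8 lower. The count was 4, 5 and 22 without control replicates 1, 2 and 3, 5 without tea 0.5% replicate 2, 15 without tea 1.0% replicate 1 and 1, Erysipelotrichaceae_incertae_sedis, without tea 1.0% replicate 3.

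At 0.5% tea no genus passed against control. The 5 genera with the smallest p were Clostridium_XI at 2.52% ± 2.03 (SD, n = 3) against 0.394% ± 0.107 in control (log2 fold change 2.67, standard error 0.70, adjusted p = 0.0634, edgeR), Dorea at 0.0127% ± 0.00556 against 0.257% ± 0.264 (-4.24, 1.31, adjusted p = 0.0720), Flavonifractor at 0.0102% ± 0.0128 against 0.434% ± 0.620 (-5.27, 1.64, adjusted p = 0.0720), Anaerofilum at 0 against 50 counts, and Lachnospiracea_incertae_sedis at 0.0999% ± 0.0613 against 1.07% ± 0.874 (-3.40, 1.14, adjusted p = 0.0742). Adjusted over the list alone, 3 of the 8 short-chain fatty acid producing Clostridia fell (Blautia, Dorea and Flavonifractor) and both tested members of the list of segmented filamentous bacteria and related genera rose. Those members are Clostridium_XI and Turicibacter, which are not themselves segmented filamentous bacteria. Turicibacter took 4.68% (interval 4.36% to 5.01%) of counts in tea 0.5% replicate 1 and 0.0615% and 0.147% in the other birds of its group (intervals 0.0334% to 0.113% and 0.0953% to 0.227%). Without adjustment 14 genera had a p under 0.05, and DESeq2 called 11 genera, 5 higher and 6 lower, TMMwsp scaling 6, and TMM scaling and a centred log-ratio with limma 0. The count was 1 without control replicate 2, 11 without control replicate 3, 1 and 2 without tea 0.5% replicates 1 and 2, and 9 without tea 1.0% replicate 1.

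Whether genera changed in step with the tea content was asked by a linear trend. The fit includes the controls, so a step from control to all tea groups can pass as well as a graded change. The genera with the steepest fitted decline per percentage point of tea were Erysipelotrichaceae_incertae_sedis, Clostridium_IV, Anaerostipes, Sharpea, Bilophila, Faecalibacterium, Flavonifractor, Clostridium_XVIII, Butyricicoccus and Anaerofustis. Sharpea was at 0 in every tea bird, so its slope is such a step, and Bilophila reached at most 0.00614% in a tea bird. Clostridium_XVIII went from 1.95% in control through 0.193% and 0.0527% to 0.0311% at 2% tea, a log2 slope of -2.91 per percentage point (standard error 0.62, adjusted p = 0.00232). The genera that increased were Jonesia, Rothia, Weissella, Aerococcus, Microbacterium, Leucobacter and Corynebacterium. Corynebacterium went from 6.42% through 11.4% and 12.2% to 18.6%, a log2 slope of 0.69 (standard error 0.23, adjusted p = 0.0317), and lay above every control in 8 of 9 tea birds. Microbacterium, an actinobacterium, went from 0.0712% through 0.0521% and 0.175% to 0.414% (log2 slope 1.41, standard error 0.43, adjusted p = 0.0211), and Leucobacter from 0.326% through 0.300% and 0.643% to 0.992% (0.89, 0.32, adjusted p = 0.0466). In all, 21 of 79 genera passed, 7 higher and 14 lower with more tea (edgeR, Benjamini-Hochberg). Of the 8 short-chain fatty acid producing Clostridia 5 declined (7 adjusted over the list alone), and of the 7 lactic acid bacteria 2 increased, Aerococcus and Weissella, while of the 8 litter genera Corynebacterium increased and Yaniella declined, with the same counts adjusted over the list alone. Clostridium_XI (log2 slope 1.10, standard error 0.43, adjusted p = 0.0587) passed upward when adjusted over its list of 2 tested genera alone. Bacteroides passed downward, but it was the only tested genus of its list, so its p was in effect not adjusted. TMM scaling gave 13 higher and 12 lower genera, DESeq2 10 and 12, and no filter on rare genera 45 calls. Without tea 1.0% replicate 1 there were 33 calls, 11 of the 21 held in each of the 12 runs that left out a bird, and Leucobacter held in 1 of them and in 5 of 11 other settings. Corynebacterium lost its call without control replicate 1, control replicate 2, tea 2% replicate 1 or tea 2% replicate 2, and under TMMwsp scaling and a centred log-ratio. Microbacterium lost its call without control replicate 1 or tea 2% replicate 2, with a replicate block and without litter genera. Rothia lost its call without tea 2% replicate 1, under DESeq2 and under a centred log-ratio. The call of Yaniella held in 7 of 10 other settings and in 6 of the 12 runs without 1 bird, and that of Anaerofustis in 6 of 10 and 5 of 12. The call of Bilophila held in 8 of 10 and 12 of 12, and that of Butyricicoccus in 10 of 10 and 9 of 12. Weissella and Sharpea lost their calls under DESeq2.

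Whether the highest and the lowest content differed was tested directly, and 1 genus passed. Erysipelotrichaceae_incertae_sedis was at 0.149% ± 0.0505 (SD, n = 3) at 0.5% tea and at 0 at 2%, at least 25.1-fold lower (edgeR adjusted p = 0.0135). Weissella, Streptococcus and Aerococcus rose and Turicibacter fell when adjusted over the list alone. The share of Turicibacter at 0.5% tea came mostly from tea 0.5% replicate 1, as given above. Streptococcus was at 0.174% ± 0.0679 at 0.5% tea and 1.04% ± 0.495 at 2% (log2 fold change 2.57, standard error 0.85, adjusted p over all genera = 0.110), and Weissella at 0.0365% ± 0.0284 and 0.496% ± 0.503 (3.73, 1.14, adjusted p = 0.110). Clostridium_XI, at 2.52% and 3.89%, did not pass (log2 fold change 0.62, standard error 0.66, edgeR adjusted p = 0.480). DESeq2 called 13 genera and a fit of the 2 groups alone 19, while TMM scaling gave 0. The call was also lost with the stricter filter and with a library size from named genera, and without any of the 3 birds at 2% tea, the count was 2 without control replicate 1 or 2, 3 without control replicate 3, 2 without tea 0.5% replicate 2 or 3, and 9 without tea 1.0% replicate 1.

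The summed shares of 7 lists of genera were then compared. Short-chain fatty acid producing Clostridia held 3.14% ± 2.23 (SD, n = 3) in control and 0.368% ± 0.278, 0.408% ± 0.494 and 0.123% ± 0.103 at 0.5%, 1.0% and 2% tea, with an exact permutation p = 0.0466 over the 4 groups (adjusted 0.307) and p = 0.0136 for all tea birds against control (adjusted 0.0848). Lactic acid bacteria held 5.79% ± 1.31, 6.59% ± 0.882, 20.7% ± 24.5 and 16.8% ± 5.63 (exact p = 0.382), with Lactobacillus at 4.56%, 4.60%, 18.2% and 12.3%, Enterococcus at 0.468%, 0.996%, 0.679% and 1.11%, and Streptococcus at 0.351%, 0.174%, 1.29% and 1.04%. The litter, skin and dust genera held 51.2% ± 23.9, 72.8% ± 4.62, 59.0% ± 28.5 and 51.5% ± 4.57 (exact p = 0.496). Within that list Brevibacterium was at 14.2%, 17.8%, 18.5% and 7.15%, Brachybacterium at 14.1%, 18.1%, 15.9% and 9.11%, and Jeotgalicoccus at 9.07%, 16.2%, 7.18% and 9.59%, and none of these passed in any contrast. Segmented filamentous bacteria and related genera held 0.446% ± 0.181, 4.15% ± 4.54, 0.834% ± 0.112 and 3.94% ± 1.57 (exact p = 0.158), and genera holding enteric pathogens, nearly all Clostridium_sensu_stricto, 0.132% ± 0.0199, 0.0360% ± 0.0207, 0.0660% ± 0.0769 and 0.0700% ± 0.0394 (exact p = 0.168). Hindgut Bacteroidetes held 0.134% ± 0.202, 0.0127% ± 0.0160, 0 and 0.0115% ± 0.0198 (exact p = 0.175). Reagent and water bacteria held 0.0204% ± 0.0290, 0.0315% ± 0.0172, 1.96% ± 3.26 and 0.335% ± 0.309 (exact p = 0.384), of which Pseudomonas made up 5.56% (interval 5.14% to 6.01%) of counts in tea 1.0% replicate 1, while Methylobacterium, Rhizobium and Brevundimonas each averaged 0.0128% or less. No list passed after adjustment over the 7 lists, and a comparison of 3 against 3 birds cannot give an exact two-sided p under 0.10.

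**Figure D2:**
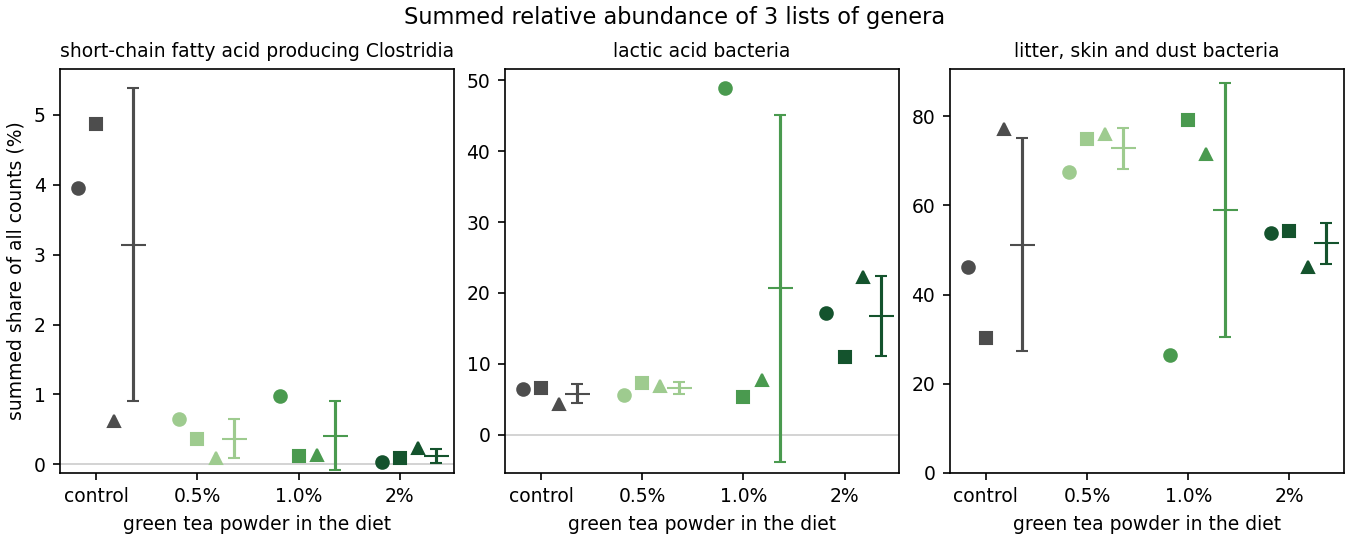
Summed share of all counts (%) of 3 lists of genera in each bird by tea content of the diet; circles, squares and triangles are replicates 1, 2 and 3, and the bars beside them are mean and SD of 3 birds. The short-chain fatty acid producing Clostridia lay at 3.95% and 4.86% in control replicates 1 and 2, at 0.621% in control replicate 3 and at 0.978% or less in the tea birds.

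OTU richness and diversity had their lowest means at 0.5% and 1.0% tea, without passing the test after adjustment. At an equal depth of 10631 counts, control birds held 434 ± 116 OTUs (SD, n = 3) and the birds at 0.5%, 1.0% and 2% tea 298 ± 34.2, 282 ± 37.4 and 387 ± 36.8. With OTUs lacking taxonomy left out, a setting added after seeing the data, the values at a depth of 9737 counts were 300.005 ± 99.8, 175 ± 32.5, 183 ± 27.2 and 209 ± 11.2 (exact permutation p = 0.110). On all counts of a bird, the Shannon index was 3.63 ± 0.621, 3.01 ± 0.126, 2.84 ± 0.214 and 3.45 ± 0.0590. The inverse Simpson index was 18.2 ± 9.70, 10.0 ± 1.04, 7.41 ± 2.84 and 16.3 ± 0.857, and Chao1 was 860.1 ± 279, 766 ± 123, 651 ± 202 and 1148 ± 129. The commonest OTU of a bird took 15.0% ± 6.30, 18.04% ± 0.814, 29.4% ± 13.0 and 12.3% ± 0.392 of its counts. Over the 4 groups the exact permutation p was 0.0614 for OTUs, 0.0747 for Shannon, 0.0918 for inverse Simpson, 0.0725 for Chao1 and 0.0294 for the commonest OTU, and none passed after adjustment over 6 measures (0.0913 to 0.0918). Control replicate 3 held 300.6 OTUs against 517 and 483 in control replicates 1 and 2. Without it the exact p was 0.00104 for OTUs and 0.000195 for the Shannon index. Without control replicate 1 or 2 the exact p was 0.127 or 0.134 for OTUs and 0.139 or 0.116 for the Shannon index.

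The composition as a whole differed between the diets. In an exact permutational analysis of variance on Bray-Curtis distances of OTU shares, the 4 groups accounted for 45.2% of the variation (pseudo-F 2.20, exact p = 0.00506). Set singly against control, with 0.1 as the smallest p that 3 against 3 birds allow, the exact p was 0.2, 0.2 and 0.1 for 0.5%, 1.0% and 2% tea, and 0.1 for 2% against 0.5%. The groups also differed in spread (exact p = 0.0334), with a mean distance to the group centroid of 0.261 ± 0.0708 in control, 0.0984 ± 0.0254 at 0.5%, 0.288 ± 0.110 at 1.0% and 0.167 ± 0.0395 at 2% tea (SD, n = 3), which the first test can also pick up. The mean distance to the control birds was 0.397, 0.488 and 0.516 for 0.5%, 1.0% and 2% tea, against 0.455 among the control birds themselves.

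**Figure D3:**
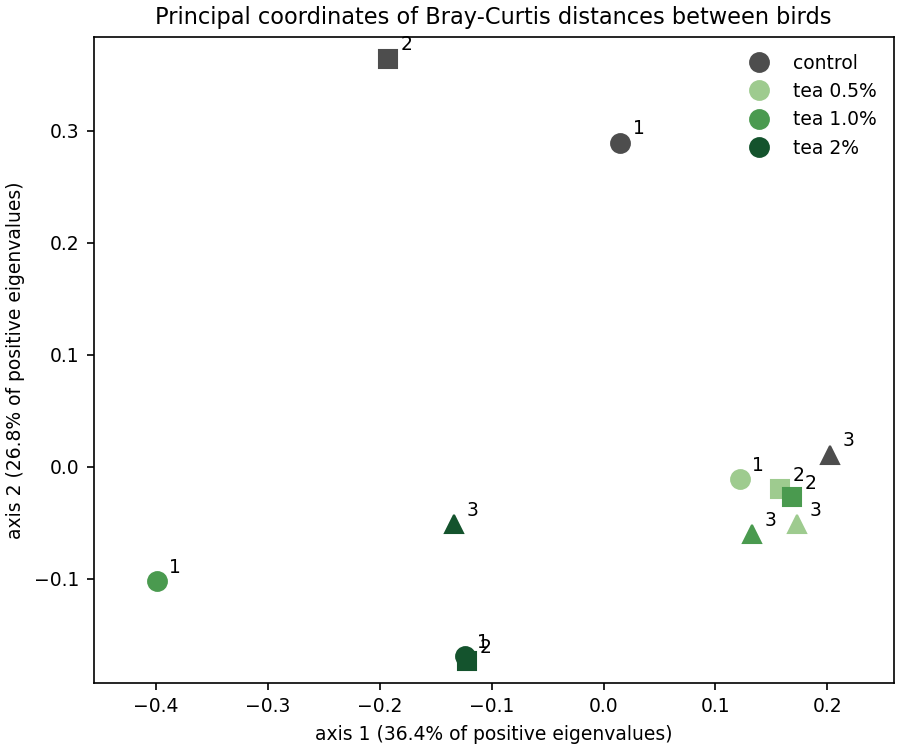
Principal coordinates of Bray-Curtis distances between the 12 birds, with axes 1 and 2 holding 36.4% and 26.8% of the positive eigenvalues; colours are diets, and symbols and numbers are replicates. Control replicates 1 and 2 lay apart on axis 2 at 0.289 and 0.365, control replicate 3 lay near the birds given 0.5% tea at 0.0109, and tea 1.0% replicate 1 lay at -0.399 on axis 1.

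At the level of single OTUs, the 5 commonest were Otu0001 (Brachybacterium, 14.3% of counts over the 12 birds), Otu0002 (Brevibacterium, 12.7%), Otu0003 (Jeotgalicoccus, 10.5%), Otu0004 (Corynebacterium, 7.82%) and Otu0005 (Lactobacillus, 7.26%). None of these 5 passed for 2% tea or for all tea birds against control. A second Corynebacterium OTU, Otu0006, rose from 1.25% ± 0.465 in control (SD, n = 3) to 2.32% ± 0.321, 3.601% ± 1.63 and 8.41% ± 2.22 with increasing tea (edgeR adjusted p = 0.00161 for 2% tea), and Otu0011 of Clostridium_XI from 0.371% ± 0.105 to 3.61% ± 1.49 at 2% tea (adjusted p = 0.00241). Among the lower OTUs with the smallest adjusted p were Otu0044 of Erysipelotrichaceae_incertae_sedis, which went from 0.722% ± 0.682 and 0.122% ± 0.0381 at 0.5% tea to 0 at 1.0% and 2%, Otu0026 of Clostridium_XVIII, from 1.79% ± 1.39 to 0.0227% ± 0.0142 at 2%, and Otu0023 of Blautia, from 1.69% ± 1.30 to 0.0604% ± 0.0492. Otu0016, a Lachnospiraceae OTU with an unclassified genus, went from 3.62% ± 4.17 in control to 0.191% ± 0.198 at 2% tea. Its control SD exceeded the mean, so the control value depends strongly on single birds. The same list held Otu0051, Otu0060, Otu0062, Otu0100, Otu0102 of Clostridium_IV and Otu0106 of Flavonifractor, each at 0.580% or less in control. Of 258 OTUs tested, 85 passed for all tea birds against control (3 higher, 82 lower), 37 for 2% tea (5 higher, 32 lower), 7 for 1.0% tea (all 7 lower) and 0 for 0.5% tea. As with genera, an OTU at 0 in a whole tea group can hardly pass as higher in the contrast of all tea birds.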

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

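The tests in this part were chosen after the pattern had been seen. OTUs without taxonomy enter no comparison of genera, and 4 of those with at least 50 counts were at 0 in all 3 control birds and seen in tea birds, above the level of the controls. Otu0038 held 559 counts, 286 in tea 0.5% replicate 2 and 273 in tea 0.5% replicate 3. Otu0039 held 531 counts, 85 in tea 0.5% replicate 1, 71 in tea 2% replicate 1 and 375 in tea 2% replicate 3. Otu0067 held 127 counts, all in tea 1.0% replicate 1, and Otu0123 held 53, all in tea 2% replicate 1. As a whole, OTUs without taxonomy were no more common with tea, at 12.2% ± 4.30 of counts (SD, n = 9) against 15.3% ± 4.37 in control (n = 3).

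These 4 belong to a wider pattern of OTUs without taxonomy that are abundant in some birds and at 0 in the rest. It was shown by 11 of the 20 OTUs without taxonomy that had at least 50 counts, against 8 of 108 with taxonomy (Fisher's exact test, two-sided p = 2.86e-06), counting OTUs with at least 5 counts wherever present and at least 10 expected wherever at 0. Presence that follows the diet group is argued against, since 0 of the 11 were present in all or none of the birds of every group. A candidate explanation is that one sequence group was divided between OTUs by sample during processing: 9 of the 11 formed 3 sets in which each bird held exactly 1 OTU of the set, Otu0010 with Otu0035, Otu0038 and Otu0067, Otu0020 with Otu0093 and Otu0103, and Otu0025 with Otu0039, and shuffling the presence patterns over birds gave 3 or more such sets with p = 0.00210, while OTUs with taxonomy formed 0. The 9 OTUs held 7931 counts, 33.5% of those without taxonomy; their sequences were not used here, so the hypothesis remains open, and single OTUs of this kind may not be separate organisms.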

How the results depend on the processing

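With 3 birds per group and 10631 to 17458 counts each, genera under about 0.02% of a bird's counts rest on 3 counts or fewer, and calls depend on single birds. The fits with families, with a library size from named genera and without litter genera, and those without OTUs lacking taxonomy, were added after seeing the data. No called genus changed direction under any setting: leaving out a bird kept 663 calls of named genera and took 141 below the threshold, and the other settings kept 593 and took 98 below it. Scalings moved the median log2 fold change of all genera by -0.33 to 0.49 across contrasts, and leaving out litter genera by -0.75 to 0.59. Changes of that size are therefore relative to the scaling. The log2 fold change of Corynebacterium at 2% tea, 1.54, was larger. Its call was still lost under TMMwsp scaling, a centred log-ratio and no filter on rare genera.

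Main counts of genera were 0, 9 and 17 for 0.5%, 1.0% and 2% tea, 19 for all tea birds, 21 for the trend and 1 for 2% against 0.5%. For 0.5% tea the count was 6 with TMMwsp, 11 with DESeq2, 7 without a filter, 2 with rarefied counts, 9 in the fit of the 2 groups alone and 3 without litter genera. For 1.0% tea it was 2 with TMM, 3 with the stricter filter, 14 with a named-genus library size and 4 with families. For 2% tea it was 37 with OTUs and 6 with families. For all tea birds it was 10 with the stricter filter, 85 with OTUs and 9 with families. For the trend it was 45 without a filter, 12 with the stricter filter, 90 with OTUs and 9 with families. For 2% against 0.5% tea it was 0 with TMM, the stricter filter, OTUs and a named-genus library size, 13 with DESeq2, 2 with the centred log-ratio, 2 without a filter, 19 in the fit of the 2 groups alone, 2 without litter genera and 4 with families. Fewer features (58 families) or more (258 OTUs) were tested in some of these; otherwise the cause was not tested. The centred log-ratio gave 1 phylum in place of 0, and the cause was not tested. Without litter genera, 2% tea gave 4 higher and 12 lower genera and the trend 4 and 17; a named-genus library size gave 5 higher and 11 lower for 2% tea; the centred log-ratio gave 10 and 13 for the trend.

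Leaving out each bird gave 0 to 11 genera for 0.5% tea, 1 to 22 for 1.0%, 7 to 27 for 2%, 15 to 23 for all tea birds, 14 to 33 for the trend and 0 to 9 for 2% against 0.5%. The exact p ranged from 0.00104 to 0.134 for observed OTUs, from 0.000195 to 0.139 for the Shannon index and from 0.000519 to 0.0405 for Bray-Curtis composition, and no phylum or list passed. Other settings gave 0.0536 to 0.110 for OTUs, 0.0709 to 0.120 for Shannon and 0.000584 to 0.0206 for composition, on the same side of 0.05 as the main values, and 0 lists. Where a group had 2 birds left, its spread was estimated with the other groups.

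Replicate numbers did not pair the birds: 5 of 18 same-number pairs correlated above 0.1 (range -0.27 to 0.414), and 4 of 12 birds correlated best with their own number. With the replicate block the counts were 9 for 0.5% tea, 11 for 1.0%, 14 for 2%, 19 for all tea birds, 17 for the trend and 3 for 2% against 0.5%, and the exact p for composition was 0.00347. Settings without chloroplast and mitochondrial OTUs were not run, since 0 OTUs were named so.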

Other observations

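The family fits, the intervals of single birds and the tests of explanations in this part were chosen after the results had been seen; the explanations for counts of genera by other splits were also written down after their results. At family level 9 of 58 families passed for all tea birds against control. Lachnospiraceae went from 8.70% ± 8.12 of counts in control (SD, n = 3) to 0.766% ± 0.603 in the 9 tea birds (edgeR log2 fold change -3.58, standard error 0.66, adjusted p = 0.000582), Ruminococcaceae from 2.63% ± 2.09 to 0.115% ± 0.119 (-4.61, 0.93, adjusted p = 0.00164) and Erysipelotrichaceae from 3.64% ± 3.06 to 0.754% ± 1.79 (-3.68, 0.76, adjusted p = 0.00152). Erysipelotrichaceae took 5.52% (interval 5.18% to 5.88%) in tea 0.5% replicate 1 and 0.369% or less in the other 8 tea birds, which without that bird had a mean of 0.158% ± 0.106 (log2 fold change -4.58, standard error 0.70, adjusted p = 2.08e-05). Eubacteriaceae, Desulfovibrionaceae (a family of sulfate reducers), Peptococcaceae_1, Coriobacteriaceae and Bacteroidaceae were also lower and Peptostreptococcaceae higher. Of these 9, Lachnospiraceae and Ruminococcaceae alone passed without control replicate 2, where Erysipelotrichaceae had an adjusted p of 0.0555. Bacteroidaceae lost its call also without control replicate 1, tea 2% replicate 2 or tea 2% replicate 3, Coriobacteriaceae without control replicate 1 or tea 2% replicate 1, and Peptostreptococcaceae without control replicate 1, tea 0.5% replicate 1 or 3, or tea 2% replicate 1 or 2. OTUs with an unclassified genus took 31.3% of counts in control replicate 2 (Wilson interval 30.5% to 32.0%) and 15.4% in control replicate 1 (14.8% to 15.9%), against 2.27% in control replicate 3 (2.03% to 2.54%), and Lachnospiraceae 17.3% (16.7% to 17.9%), 7.62% (7.21% to 8.04%) and 1.17% (1.00% to 1.37%).

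Some taxa were common in single birds. Clostridiaceae_1, a family that includes Clostridium sensu stricto, took 11.8% of counts (11.3% to 12.3%) in tea 2% replicate 2 and 3.18% (2.93% to 3.46%) in tea 2% replicate 1. It took 2.92% (2.61% to 3.25%) in tea 1.0% replicate 1 and 0.239% or less in the other 9 birds. The family was among 4 that passed for 2% against 0.5% tea (log2 fold change 6.26, standard error 1.76, adjusted p = 0.0437, edgeR). OTUs with an unclassified genus, which enter no genus test, held 13.2% in tea 2% replicate 2. Clostridium_sensu_stricto made up little of the family. The pathogen list, nearly all that genus, held 0.0301%, 0.109% and 0.151% in these 3 birds, in the order given. The same 3 birds were those with Otu0033 of Pseudomonas (580, 92 and 39 counts in tea 1.0% replicate 1, tea 2% replicate 1 and tea 2% replicate 2) and Otu0053 of Streptococcus (189, 66 and 12), each at 0 in the other 9; these OTUs were chosen after their values were seen. Enterobacteriaceae, the family of Escherichia and Salmonella, had 46 counts in the 12 birds, 27 of them in tea 1.0% replicate 1.

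The lower share of the 17 genera with tea invites the question of what carries it. Dilution by litter bacteria is argued against: among counts outside the litter list the 17 lower genera held 13.4% ± 7.83 in control (SD, n = 3) and 1.53% ± 1.47 in tea (n = 9), a log2 ratio of -3.14, and all 17 passed again without litter counts. That 2 of the 3 control birds carry the difference is compatible with the shares, since control replicate 3 lay at or below the highest tea bird in 13 of the 17 genera. Setting 1 bird against the highest of 9 is a weak test, and control replicate 3 lay above the mean of the tea birds in 10 genera. Diet, the room of each group and, as an untested possibility, hindgut material in the ileal samples of those birds all remain open, because the groups are not tied to rooms in the labels and 3 controls do not show how often a control bird has few of these genera.

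Litter, skin and dust genera made up 58.6% ± 18.5 of counts (SD, n = 12), from 26.4% to 79.1%. The listed reagent and water bacteria were a small part of the counts, since the reagent list stayed below 1% in 11 of the 12 birds. That list holds none of the litter, skin and dust genera. Its share therefore cannot tell whether those genera came in at extraction, and no blank was among the samples. The hypothesis of 1 source with 1 mix of the litter, skin and dust genera for every group was tested on the mix found in the birds. Shares within the litter list, over all 10 genera seen, differed between the 4 groups (exact permutational analysis of variance, p = 0.000195, 75.7% of the variation). Their spread did not pass (exact p = 0.218). A first form of this test also asked for a p under 0.05 without Corynebacterium and Brevibacterium, which was not met (exact p = 0.130). That bound was given up after its value was seen, since 1 mix would have to hold for all 10. The same mix in the birds of every group is thus argued against, with the difference resting largely on these named genera. Whether there was 1 source cannot be told from this test, since shares may also change within the gut. Swallowed bedding, bacteria living in the ileum and carry-over at sampling, which may each differ by room or by diet, were not tested.

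Other splits of the birds show how often a count of genera as large arises, with the real split among those counted. For all tea birds against control, 2 of 100 splits gave as many genera as the real 19, the highest other 20. For the trend 2 of 100 gave as many as the real 21, the highest other 21. The share was under 0.05 in both, though with so few draws it is itself uncertain. These splits treat all birds as interchangeable, so differences between rooms were not tested. With 3 birds against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 0 and 1 for 0.5% tea (10 of 10 splits gave as many), 9 and 16 for 1.0% (2 of 10), 17 and 1 for 2% (1 of 10) and 1 and 1 for 2% against 0.5% tea (2 of 10). The split with 16 set control replicates 1 and 2 and tea 1.0% replicate 1 against the others, a structure of the birds that does not follow the diet.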
